A study of Mus musculus with 192 samples.

How the data were processed

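The series holds single-cell RNA sequencing of mouse intestinal epithelial cells sorted by EpCAM and by a Clu-EGFP reporter. Per the labels' protocols, about 2000 sorted cells of each kind were loaded on a Fluidigm C1, a microfluidic instrument that captures single cells, and 96 GFP+ and 96 GFP− cells were selected. Full-length cDNA was made with a SMART-Seq V4 kit, which has no unique molecular identifiers and does not mark strand. Each sample in the series was 1 cell. Cells were assigned to GFP+ or GFP− from the labels, and their plate from the same labels. No cell was left unassigned.

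The authors deposited a table of raw read counts for 32196 genes in 96 GFP+ and 96 GFP− cells and a processed table for 16500 genes in 166 cells. The submitters' processing notes name STAR, featureCounts and Seurat and the genome builds mm10 and GRCm38, without versions or roles. The annotation, strand setting and handling of reads that map to several places are not given in the sources used here. From its values, the deposited processed table holds log2 of a scaled count plus 1, with 1 scale factor per cell that gives each cell the same total, and it holds none of the 34 mitochondrially encoded genes. It covers 84 GFP+ and 82 GFP− cells, so 12 and 14 cells were left out by the authors. No row lacked a gene name, no column was left unused, and no 2 cells had identical counts. Values of EGFP were not analysed here.

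The cell filter, gene lists, naming rule and cell type markers were set before the data were examined, and the cell filter had to be dropped. The planned cell filter asked for at least 1000 genes, at least 50000 counts and at most 30% of counts from mitochondrially encoded genes, and CPM were to be taken of all counts. All cells of both groups passed the first 2 limits, but the limit of 30% left 21 GFP+ and 2 GFP− cells. All values given as main results therefore use all cells and CPM of non-mitochondrial counts, a choice made after the mitochondrial shares were seen. The use of all cells had itself been listed among the alternatives beforehand. The planned filter and totals with mitochondrial genes are reported as alternatives. Keeping mitochondrial genes in the totals adds 0.68 to every log2 ratio. A high mitochondrial share can come from damaged cells or from cell types rich in mitochondria, and it reduces the counts left for other genes.

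Counts were summed over the cells of a group and divided by the summed non-mitochondrial total, 199930198 for GFP+ and 91706003 for GFP− cells. Pooled CPM have exact 95% Poisson intervals, log2 ratios an interval from the exact binomial split of the 2 sums, and shares of cells exact Clopper-Pearson intervals. All of these cover counting error only. Reads without molecular identifiers are not independent molecules, so the true error is wider. A group with no read of a gene was set to a floor of 3 counts over the group. Because cells are not replicates and no animal is named, no p-value was computed. Detection was the share of cells with a read after thinning to 510000 non-mitochondrial reads per cell, the 10th percentile of totals over cells rounded down to a multiple of 10000, which left out 4 GFP+ and 16 GFP− cells.

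For 32 fixed gene lists, the median log2 ratio was taken over members with a mean pooled CPM of at least 1 in the 2 groups. It was given with an order-statistic 95% interval where at least 6 members were measured, with the range otherwise, and with its percentile among 10000 random lists matched on mean level in 20 bins. The list of mitochondrially encoded genes is reported as a share of counts. The named genes were, per direction, the 12 with the largest ratio among genes with at least 20 CPM and at least 30% detection in the higher group. Detection had to be at least 20 percentage points higher there, no cell could hold more than 25% of the higher group's counts, and the ratio with cells weighted equally had to have the same sign. The lower group had no such limit, and 1 cell held 91.6% of the GFP+ counts of Rhod, a gene named in GFP− cells. Predicted genes and pseudogenes were left out by symbol. The rule for examples was to take 2 to 4 members of each list with the highest level in either group, but for some lists fewer or none are given. Ace2, Slc5a1, Krt18, Irf7, Itgb4, Pmaip1, Plk2, Axin2, Msln and Tacstd2 lie outside this rule and were chosen after their values were seen, as were the genes in the plot of levels per cell.

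Cells were clustered together on log2(CPM/10 + 1) of the 2000 most variable genes, with 15 principal components, 10 neighbours and Leiden clustering at resolution 1.0. A cluster was named for a class when at least 3 of its fixed markers were higher by at least 1 in mean log2(CPM/10 + 1) than in other cells and detected in at least 30% of its cells, with no tie and no more markers of another class among its top 10 genes. That scoring rule was set after the files were seen. No doublet caller was run at this number of cells, and doublets were not removed.

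Gene coordinates are 1-based from the GENCODE M21 annotation of GRCm38, matched by symbol for 32104 of 32162 non-mitochondrial symbols. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9 were used, with TMM factors from edgeR 4.0.16 in R 4.3.3 as an alternative scaling. The ratio step was tested on counts simulated for the GFP+ against GFP− comparison over 32162 genes. Of 50 genes per step with true log2 ratios of 2, 1, -1 and -2, the median estimates were 1.99, 1.04, -1.13 and -2.07. Alternatives covered the cell filter, the weight of cells, scaling, low-level genes, the deepest cell, the authors' table, clustering settings and the detection limit. After seeing the data, the authors' cells, thinned counts, cells with 50 to 80% mitochondrial counts, totals with mitochondrial genes, the top cell of each gene and clustering without marker genes were added.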

Results

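Single intestinal epithelial cells of mice carrying a Clu-EGFP reporter were profiled by full-length RNA sequencing after EpCAM-based sorting. The reporter is a bacterial artificial chromosome transgene in which enhanced green fluorescent protein marks cells using the promoter of Clu, the gene of the secreted chaperone clusterin. The series title names the tissue as regenerating intestine and a revival stem cell as its subject, and the labels state no injury, dose or day. The deposited tables held 96 GFP+ cells, all from plate 3, and 96 GFP− cells, all from plate 4. No animal was named for any cell, so each group counted as 1 sample. Values are therefore given for both groups with counting error only, and no test between GFP+ and GFP− cells was made. Plate and group cannot be told apart.

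Total counts per cell had a median of 4687417 in GFP+ cells (range 418991 to 15867593) and 3936645.5 in GFP− cells (range 980250 to 7978845). Mitochondrially encoded genes took a median of 55.2% of a cell's counts in GFP+ cells and 75.1% in GFP− cells. What remained was a median of 1509113 non-mitochondrial counts and 2637 genes in GFP+ cells, against 850469.5 and 2364.5 genes in GFP− cells. Levels are given as CPM, the counts of a gene summed over the cells of a group and scaled to a total of 1000000 non-mitochondrial counts. The median log2 ratio of GFP+ over GFP− over the 13527 measured genes was -0.44 on this scale, and it was 0.17 with TMM factors and 0.24 with mitochondrial genes kept in the totals. Both scalings raise every log2 ratio alike, by 0.60 and 0.68, so that genes closer to 0 than that on the negative side change sign under them.

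**Figure D1:**
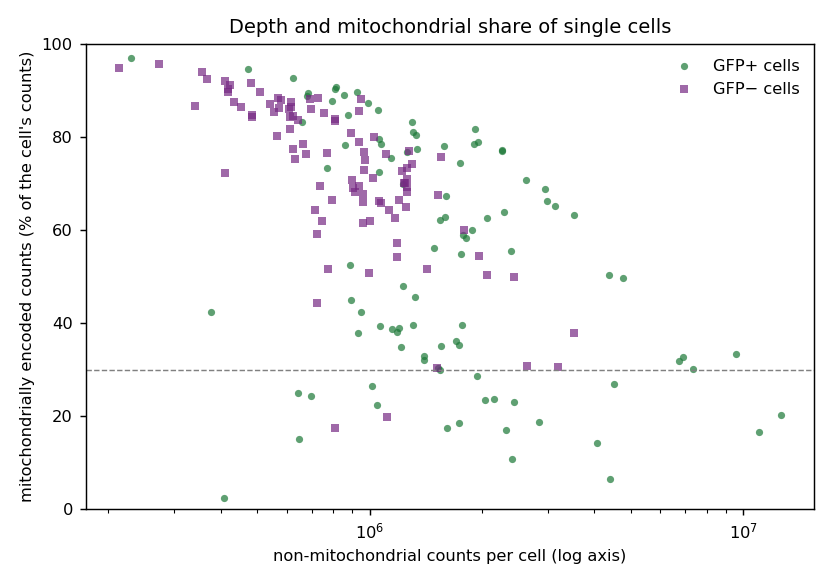
Each point is 1 cell, with its non-mitochondrial counts on a log axis and the percentage of its counts from mitochondrially encoded genes on the other axis, for 96 GFP+ cells (circles) and 96 GFP− cells (squares). The dashed line is at 30%, and 21 GFP+ cells and 2 GFP− cells lay at or below it.

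The first question was whether the sorted cells carried the transcript that drives the reporter. Clu (chromosome 14, 65968483 to 65981547, plus strand, GRCm38) stood at 755.9 CPM (95% Poisson interval 752.1 to 759.7) in GFP+ cells and at 7.83 CPM (7.27 to 8.42) in GFP− cells, a log2 ratio of 6.59 (6.49 to 6.70). Because the cells were sorted on this reporter, the value checks the labels and is no finding. The level was uneven, with a median GFP+ cell at 19.1 CPM and 1 GFP+ cell holding 31.1% of the GFP+ Clu counts. The log2 ratio was 9.84 among the 21 GFP+ and 2 GFP− cells with at most 30% mitochondrial counts, 5.27 in the authors' processed table, and 3.71 among the 33 GFP+ and 51 GFP− cells with 50 to 80% mitochondrial counts.

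After each cell was thinned to 510000 non-mitochondrial reads, at least 1 Clu read was found in 91.3% of 92 GFP+ cells (exact binomial interval 83.6 to 96.2%) and in 47.5% of 80 GFP− cells (36.2 to 58.98%), and at least 3 reads in 72.8% and 25%. Without thinning the shares with at least 1 read were 94.8% and 54.2%. Reads of the genes abundant in GFP+ cells also occurred in the GFP+ cells of the enterocyte-like clusters described further on. Of 18 such cells, 14 had at least 1 thinned Clu read, at a pooled 18.7 CPM that was 1.61% of the level in the GFP+ cells of the revival stem cell-like clusters, with 71.1% of those 18 cells' Clu counts in 1 cell. For Ly6a the 18 cells stood at 0.911% of that level, with reads in 11 of them, and for Cyp51 at 49.4%, with 76.5% of those Cyp51 counts in 1 cell. A share of cells with a read is given below as detection, not as the share of cells expressing a gene.

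The main comparison asked which transcripts set GFP+ cells apart from GFP− cells. GFP+ cells had far more RNA of Ly6a, which encodes the surface antigen Sca-1, and of Cd44, the hyaluronan receptor. They also had more RNA of F3, the coagulation initiator tissue factor, and of the simple-epithelium keratins Krt18 and Krt19. GFP− cells had more RNA of absorptive genes such as Slc2a2, which encodes the glucose transporter GLUT2, and Slc7a9, a subunit of the cystine and dibasic amino acid transporter. Ly6a (chromosome 15, 74994877 to 74998031, minus strand) was at 1509 CPM in GFP+ cells and 0.469 CPM in GFP− cells, a log2 ratio of 11.65 (11.22 to 12.12), with reads in 84.8% and 17.5% of thinned cells. Its level was uneven, with a median GFP+ cell at 9.27 CPM and 1 GFP+ cell holding 24.8% of the GFP+ Ly6a counts. Cd44 (chromosome 2, 102811141 to 102901665, minus strand) was at 434.6 and 1.57 CPM, a log2 ratio of 8.11 (7.88 to 8.36), with reads in 89.1% and 22.5% of thinned cells.

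The rule for named genes gave 11 further genes in GFP+ cells besides Ly6a, of which Cd44 had the smallest ratio. Fndc3b (100.8 against 0.0872 CPM, log2 ratio 10.17) and Spred1, an inhibitor of Ras signalling (173.3 against 0.251 CPM, 9.43), followed Ly6a. Zkscan6 (9.39), Cyp51, the lanosterol demethylase of cholesterol synthesis (9.04), the keratin gene Krt23 (8.67) and Dusp1, a phosphatase of MAP kinases (8.53), came next. The others were Nup133 of the nuclear pore (8.48), Dtx4 (8.32), Stox2 (8.31) and the kinase gene Nek7 (8.20). Each of the 12 was higher in GFP+ cells under every alternative tried, with log2 ratios between 3.998 for Dtx4 and 12.33 for Ly6a. The 12 were chosen in these same cells for the largest ratios, so a kept sign is no independent support.

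The 12 genes named in GFP− cells were Ppm1a, Cyp3a11, Slc2a2, Rhod, Lmtk2, Slc7a9, Clec2e, Dnah8, Pi4ka, Khk, Nostrin and Cit. Cyp3a11, a cytochrome P450 of drug metabolism, was at 641.2 CPM in GFP− cells and 56.6 CPM in GFP+ cells (log2 ratio -3.50). Slc2a2 (chromosome 3, 28697903 to 28731359, plus strand) was at 332.6 and 31.04 CPM (-3.42), Slc7a9 at 213.7 and 22.4 CPM (-3.25), and Khk, the ketohexokinase of fructose breakdown, at 153.0 and 17.9 CPM (-3.09). Ratios for the 12 ran from -3.93 for Ppm1a to -2.91 for Cit. With the limit of 30% mitochondrial counts, which left 2 GFP− cells, 9 of the 12 had the opposite sign, and Cyp3a11, Dnah8 and Cit kept theirs. For a gene with no read in those 2 cells the floor of 3 counts can keep the sign. Reads of Cyp3a11 and Clec2e can be shared with close paralogs.

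**Figure D2:**
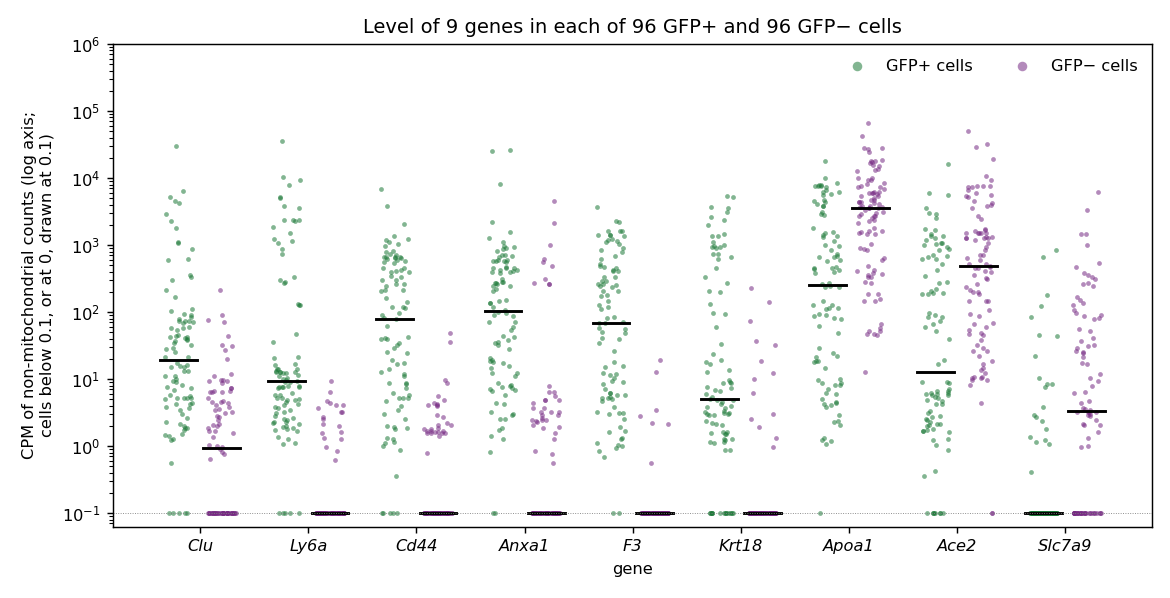
Each point is 1 cell's CPM of non-mitochondrial counts (log axis) for 9 genes, with 96 GFP+ cells (left of each pair) and 96 GFP− cells (right). Black bars are medians over cells, and cells below 0.1 CPM are drawn at 0.1. The median GFP+ cell had 79.5 CPM of Cd44 and 254.5 CPM of Apoa1, and the median GFP− cell had 0 CPM of Cd44 and 3601 CPM of Apoa1.

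Genes tied to epithelial repair stood higher in GFP+ cells. All 5 members of the revival stem cell list other than Clu were higher, with a median log2 ratio of 2.48 (range over members 0.73 to 3.69). They were the annexin gene Anxa1 (1186 against 92.1 CPM), the laminin subunit gene Lamc2 (911.6 against 254.1 CPM), Cxadr (376.0 against 67.4 CPM), Basp1 (77.8 against 11.6 CPM) and the EGF receptor ligand gene Areg (500.7 against 302.9 CPM). Among 10000 random lists of like size and level this median was at percentile 96.4, and at 90.4 with cells weighted equally, where it was 1.66. All 11 measured genes of the fetal and repair epithelium list were higher, with a median of 7.64 (0.57 to 11.66) above all 10000 random lists. Among these were the calcium-binding S100a6 (1799 against 327.3 CPM), Anxa3 (738.3 against 3.71 CPM) and Il1rn, the interleukin 1 receptor antagonist (355.5 against 1.40 CPM). For Msln and Tacstd2 1 GFP+ cell held 84.1% and 99.8% of the counts. Median detection over the 11 genes was 19.6% of GFP+ and 3.75% of GFP− cells. The revival stem cell median was 8.39 with 21 and 2 cells, 1.42 with thinned reads and 1.32 among cells with 50 to 80% mitochondrial counts, and the fetal and repair median 5.73 with 21 and 2 cells and 4.94 at 50 to 80%.

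The basement membrane and wound edge list was higher for 9 of 10 members, with a median of 2.78 (1.17 to 7.55, percentile 99.7), and of 5.75 with 21 and 2 cells. The integrin genes Itga6 (775.8 against 134.7 CPM) and Itgb6 (437.2 against 84.1 CPM) led by level, and Itgb4 was the exception at -0.19, a sign that turned under TMM factors. For Itgb6 1 GFP− cell held 92.3% of the GFP− counts, and its log2 ratio went from 2.38 to 5.03 without top cells. Targets of p53, the transcription factor of the DNA damage response, were higher for 13 of 15 members with a median of 3.32 (0.71 to 5.31, percentile 99.97). That median was 1.96 over genes with a pooled CPM of at least 10, 2.52 at 50 to 80% mitochondrial counts and 5.04 without top cells. Median detection over the members was 19.6% of GFP+ and 8.75% of GFP− cells. Mdm2, the ubiquitin ligase that degrades p53, was at 323.6 against 19.7 CPM, Ccng1 at 774.1 against 101.01 CPM, and Cdkn1a, the cell cycle inhibitor p21, at 397.9 against 202.8 CPM. In GFP− cells 1 cell held 85.6% of the Mdm2 counts and 1 cell 74.7% of the Ccng1 counts. Without top cells their log2 ratios went from 4.04 to 6.30 and from 2.94 to 4.25. Perp was at 1326 against 59.6 CPM, with 61.1% of its GFP+ counts in 1 cell, while Pmaip1 (-0.58, a sign that turned under TMM factors) and Plk2 (-0.73, but 0.38 without its top cells) were lower. Of 17 measured targets of the coactivator YAP, 9 were higher and 8 lower (10 and 7 under TMM factors), with a median of 0.43 (-3.48 to 1.59, percentile 80.9) that turned to -0.15 with cells weighted equally, -0.39 with thinned reads and -1.19 at 50 to 80% mitochondrial counts. Within that list F3 (383.1 against 0.414 CPM, detection 91.3% and 6.25%) and Myof (135.1 against 24.7 CPM, 84.8% and 11.2%) were higher in GFP+ cells.

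Markers of other crypt states went both ways. The crypt base columnar stem cell list had 3 of 9 members higher and a median of -0.94 (-3.30 to 5.75, percentile 30.1). The sodium, potassium and chloride cotransporter gene Slc12a2 (224.0 against 4.18 CPM) and Prom1 (135.3 against 1.54 CPM) were higher in GFP+ cells. Lgr5, the receptor that marks these stem cells, was at 475.4 against 293.6 CPM, but 1 GFP+ cell held 85.6% of its counts and its log2 ratio went from 0.70 to -1.51 without the top cell of each group. The median of the list was -4.19 among cells with 50 to 80% mitochondrial counts. In the position +4 reserve stem cell list, with a median of 1.09 over 4 members (percentile 79.6), Sox9 was at 40.1 against 6.19 CPM with detection of 77.2% and 7.50%. That median turned to -0.27 with cells weighted equally, -0.39 with thinned reads and -2.33 among cells with 50 to 80% mitochondrial counts. The proliferation list had 10 of 17 members higher and a median of 0.71 (-0.99 to 4.99, percentile 88.01), which was -2.16 with 21 and 2 cells. Its most abundant member, Tyms, was at 191.8 against 380.5 CPM, with 81.1% of its GFP+ counts in 1 cell (log2 ratio -0.99, and -2.97 without its top cells), and Pcna was at 87.2 against 2.75 CPM.

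Wnt targets had a median of -0.88 (5 of 11 higher, percentile 30.3), which turned to 0.18 with cells weighted equally (percentile 70.8) and 0.46 without top cells, with Cd44 and Ccnd1 (148.0 against 19.9 CPM) higher and Axin2 (1.45 against 13.9 CPM) lower. Notch pathway genes had a median of -2.36 (2 of 6 higher, percentile 12.4), with Hes1, a transcriptional repressor induced by Notch, at 726.7 against 42.4 CPM and Jag1 at 13.98 against 58.6 CPM. Many of the low-level genes in these lists were read in few cells.

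Absorptive enterocyte genes were lower in GFP+ cells but were far from absent there. Of 19 measured members, 16 were lower, with a median of -0.98 (-1.59 to -0.20, percentile 2.58). With TMM factors or with mitochondrial genes in the totals, 12 of the 19 were lower and the medians were -0.38 and -0.31. With cells weighted equally the median was -0.53 (percentile 13.2), among cells with 50 to 80% mitochondrial counts -0.22, and with 21 and 2 cells 0.41. The apolipoprotein gene Apoa1 was at 2095 against 6296 CPM (log2 ratio -1.59), Ace2 at 576.7 against 2623 CPM (-2.19) and the glucose cotransporter gene Slc5a1 at 1220 against 3046 CPM (-1.32). The fatty acid binding protein gene Fabp1 was higher in GFP+ cells (8688 against 5723 CPM, 0.60), and Fabp2 was lower (6870 against 8950 CPM, -0.38), with the sign of Fabp2 turning under TMM factors. The villus tip list had a median of 0.10 (3 of 6 higher, percentile 54.9), with Ada, the adenosine deaminase gene, at 2237 against 2638 CPM, a sign that turned under TMM factors.

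Secretory lineages gave sparse values. The goblet cell list was lower for 6 of 8 members, or 5 under TMM factors, with a median of -1.92 (-10.05 to 7.22, percentile 5.23), or -0.76 with the authors' cells. The mucin gene Muc2 was at 2.19 CPM in GFP+ cells and 356.3 CPM in GFP− cells, where it was read in 5.43% and 41.2% of thinned cells, and Zg16 was at 356.3 against 819.0 CPM. For Paneth cells the median was 3.93 over 4 genes (percentile 97.2), and -2.79 with 21 and 2 cells. Mmp7, which encodes matrilysin, was at 274.0 against 0.153 CPM, with 69.3% of its counts in 1 GFP+ cell, and 1 cell also held 90.8% of the GFP+ counts of the defensin gene Defa24. The enteroendocrine median was 1.56 (4 genes, percentile 84.9), or -1.61 with no filter on low genes, and the tuft cell median -1.87 (5 genes, percentile 34.2), or -0.05 with the authors' cells, and 1 GFP+ cell held 99.1% of the counts of Scg5, the enteroendocrine gene with the highest level.

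**Figure D3:**
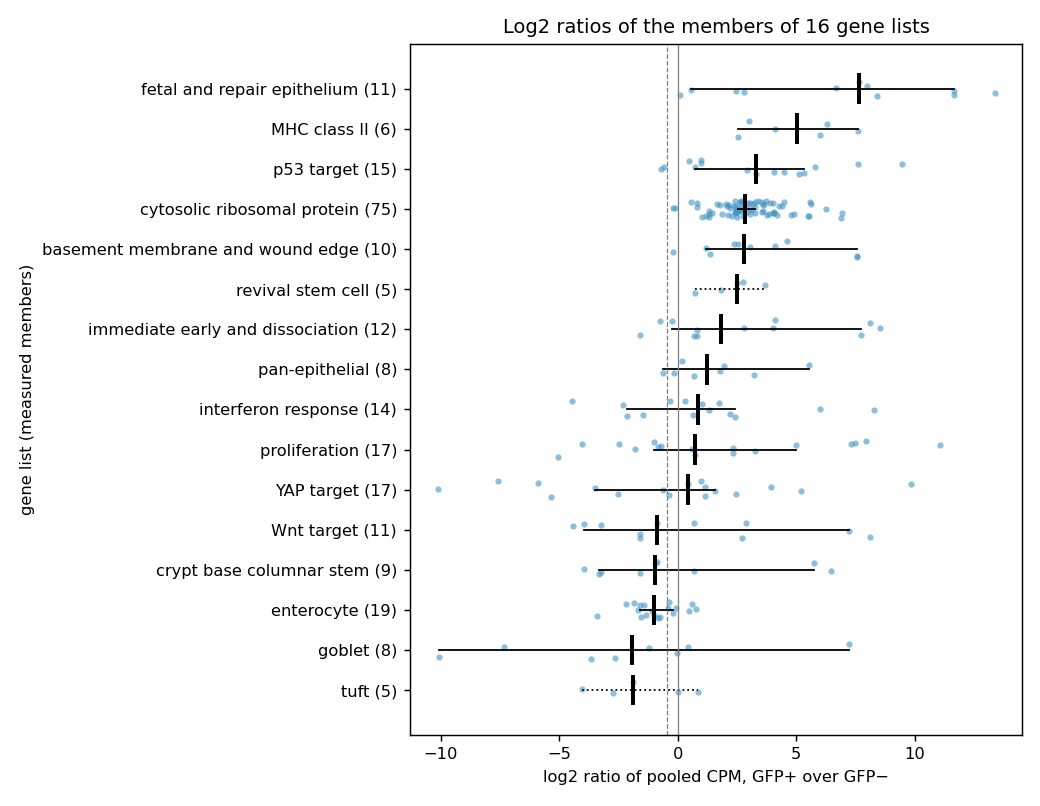
Log2 ratios of pooled CPM, GFP+ over GFP−, for the measured members (points, numbers in parentheses) of 16 gene lists, with heavy bars at list medians. Solid lines are 95% order-statistic intervals of the median over members and dotted lines the range of lists with under 6 members, and the dashed line at -0.44 is the median of all measured genes. The fetal and repair epithelium list had a median of 7.64 and the enterocyte list of -0.98, the latter -0.38 under TMM factors.

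Ribosomal and antigen presentation genes also differed between the groups, alongside the higher mitochondrial share of GFP− cells, while stress genes were less clear. Cytosolic ribosomal protein genes were higher in GFP+ cells for 73 of 75 members, or all 75 under TMM factors, with a median of 2.82 (2.55 to 3.25) above all 10000 random lists, and their summed level was 27448 against 4507 CPM. Reads of these genes can be shared with processed pseudogenes. All 6 MHC class II genes were higher, with a median of 5.04 (2.52 to 7.58, percentile 99.5), which was 0.02 with 21 and 2 cells and 2.39 among cells with 50 to 80% mitochondrial counts. Cd74, the invariant chain, was at 118.5 against 1.88 CPM and H2-Ab1 at 113.1 against 19.7 CPM. The other genes of the list were read in few GFP+ cells, H2-Aa in 13, H2-Eb1 in 10, H2-DMa in 8 and Ciita in 6. Median detection over the list was 10.3% of GFP+ and 3.125% of GFP− cells. Immediate early and dissociation genes, the stress list, had a median of 1.81 (9 of 12 higher, 10 under TMM factors, percentile 98.3). Its interval of -0.24 to 7.71 reached negative values, and the median was 0.81 over genes with a pooled CPM of at least 10. Fos was at 406.2 against 229.7 CPM, Dusp1 at 121.1 against 0.327 CPM and Junb lower at 52.4 against 89.2 CPM.

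Interferon response genes had a median of 0.83 (9 of 14 higher, 10 under TMM factors, percentile 91.5), with Oasl2 at 999.7 against 297.3 CPM and Irf7 at 24.6 against 67.5 CPM. Pan-epithelial genes had a median of 1.25 (6 of 8 higher, 7 under TMM factors, percentile 90.9). Krt18 (559.7 against 12.3 CPM) and Krt19 (887.4 against 94.3 CPM) were higher, and Epcam, whose protein was used for sorting both groups, was close (2164 against 1888 CPM). The level of Krt18 was uneven, with a median GFP+ cell at 4.99 CPM and 37 of 96 GFP+ cells at 10 CPM or more. The antimicrobial lectin gene Reg3b was among the most abundant transcripts of both groups at 23247 and 23069 CPM, while Reg3g was at 6368 against 965.3 CPM, in a list with a median of 0.01 (percentile 55.1). Reads of Reg3b and Reg3g can be shared between these paralogs. Proximal and distal small intestine lists had medians of 0.17 (percentile 59.2) and 0.02 (percentile 59.5), with Onecut2 at 437.5 against 45.9 CPM, and no gene of the colon list reached the minimum level.

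Markers of non-epithelial cells were mostly low and read in few cells. Medians were -6.09 for T and NK lymphocytes (percentile 3.17), -10.51 for B and plasma cells (percentile 0.12), 0.22 for myeloid cells (percentile 66.3), -6.68 for fibroblasts and muscle (percentile 2.37), -5.92 for endothelium (percentile 3.29) and 3.68 for 1 erythroid gene (percentile 83.4). The most abundant were Vim, at 108.9 CPM in GFP− cells and no read in GFP+ cells, and Emcn, at 100.98 CPM in GFP− cells and 0.245 CPM in GFP+ cells. In GFP− cells 1 cell held 97.6% of the Vim counts and 1 cell 96.0% of the Emcn counts, but Cd79a was read in 9 GFP− cells and Pecam1 in 16. Without the top cell of each group for each gene the medians were 0.46 for T and NK lymphocytes, -5.45 for B and plasma cells, -1.80 for myeloid cells, -5.47 for fibroblasts and muscle and -4.79 for endothelium. The 0.46 is the value of Cd3e, whose reads in GFP+ cells all came from 1 cell. With that cell left out GFP+ cells stood at the floor of 3 counts, so 0.46 gives no direction. In the authors' processed table T and NK lymphocytes were at -2.89 and fibroblasts and muscle at -0.58, and with no filter on low genes at -1.52 and -1.24. With no such filter B and plasma cells were at -1.71, myeloid cells at -0.22 and endothelium at -5.81. Medians over genes with so few reads can be set by the floor of 3 counts.

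Clustering of all cells gave 8 clusters. Clusters 1, 4 and 8 carried markers of the revival stem cell list and Clu, on whose reporter the cells were sorted. Besides Clu, Anxa1, Areg and Lamc2 were higher in all of these clusters, which were called revival stem cell-like. They held 52 of 96 GFP+ cells (54.2%, exact binomial interval 43.7 to 64.4%) and 1 of 96 GFP− cells (1.04%, 0.0264 to 5.67%). Clusters 2, 3 and 7 carried enterocyte markers and were called enterocyte-like, with 18 GFP+ cells (18.8%, 11.5 to 28%) and 77 GFP− cells (80.2%, 70.8 to 87.6%). Of those GFP− cells, 41 lay in cluster 3, which was led by Zg16, a gene of the goblet list, and by Apoa1. In cluster 3, 7 enterocyte markers were higher, against 16 in cluster 2. Its median cell had 1847 genes and 80.9% mitochondrial counts, and the authors kept 32 of its 43 cells. The median mitochondrial share was 36.6% in the GFP+ cells of the revival stem cell-like clusters, and 66.8% and 74.2% in the GFP+ and GFP− cells of the enterocyte-like clusters. Cluster 5, led by Gm11400, Sfi1 and Pcdh15, held 12 GFP+ and 17 GFP− cells, and cluster 6, led by Reg3g and Reg3b, held 14 GFP+ cells and 1 GFP− cell, and neither was named. In 1 alternative all marker genes, Clu among them, were left out of the clustering but still used to name clusters. Revival stem cell-like clusters then held 57.3% of GFP+ and 1.04% of GFP− cells, and enterocyte-like clusters 14.6% and 80.2%. The sort on the Clu reporter can set these shares, and a cluster of 1 plate may be that plate. The GFP− share in enterocyte-like clusters ranged from 43.8% to 98.96% over other clustering settings and the authors' cells.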

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

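The settings with the authors' cells, thinned reads, 50 to 80% mitochondrial counts, mitochondrial genes in the totals, the top cell of each gene left out and clustering without markers were chosen after seeing the data. Of 386 alternative list medians, 352 stayed within the interval of the main value, 29 moved and 5 reversed, and of 264 alternative ratios of named genes 105, 150 and 9 did so. The sign changed in 43 of the 386, more than the 5 because lists with under 6 members were held against the range of their members and because many intervals included 0. No paired analysis was possible because each group is 1 sample and no test was made. The stricter cell filter left no GFP− cell and gave no value. Depth limits genes read in few cells, and intervals over reads understate their error.

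The planned limit of 30% mitochondrial counts left 21 GFP+ and 2 GFP− cells, so its values rest on 2 GFP− cells. It gave 9.84 for Clu (main value 6.59), 8.39 for the revival stem cell list, -2.16 for proliferation, 6.81 for ribosomal protein genes (2.82), 6.59 for pan-epithelial genes (1.25), 3.54 for the interferon response (0.83), 0.02 for MHC class II (5.04), 3.51 for the proximal small intestine (0.17), -4.31 for myeloid cells (0.22), -3.43 for B and plasma cells (-10.51), -2.79 for Paneth cells (3.93) and 3.42 for the Notch pathway (-2.36), and reversed values of 0.41 for the enterocyte list and -4.60 for the erythroid gene. It also reversed Ppm1a (1.72), Slc2a2 (1.92), Rhod (1.46), Lmtk2 (2.67), Slc7a9 (1.57), Clec2e (4.40), Pi4ka (3.72), Khk (3.49) and Nostrin (5.57). The -4.60 of the erythroid gene was also the median of the T and NK lymphocyte, fibroblast and muscle and endothelial lists. With no read in the 2 GFP− cells, the floor of 3 counts can make a gene with few GFP+ reads appear lower in GFP+ cells. The negative values of sparse lists in this setting therefore give no direction.

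The Clu ratio was 6.35 with cells weighted equally, 7.20 with TMM factors, 7.27 with mitochondrial genes in the totals, 5.27 in the authors' processed table, 6.32 with the authors' cells, 6.35 with thinned reads and 3.71 at 50 to 80% mitochondrial counts. TMM and mitochondrial totals add 0.60 and 0.68 to every ratio by construction, and for the others the cause was not tested. At 50 to 80% mitochondrial counts the crypt base columnar list was at -4.19 and the erythroid gene at -5.38. The erythroid value was -1.71 with no filter on low genes and -0.12 without its top cells, since 1 GFP+ cell held 99.4% of Hba-a1. With no such filter the B and plasma cell and antimicrobial lists also had -1.71, a value that the floor of 3 counts can set. With at least 3 reads, Clu detection was 72.8% and 25%.

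Enterocyte-like shares of GFP+ and GFP− cells were 32.3% and 98.96% at resolution 0.5, and 7.29% and 43.8% with 1000 genes. The GFP− share was 52.1% at resolution 1.5 and 54.9% with the authors' cells, and the cause was not tested. Revival stem cell-like shares stayed between 47.6% and 57.3% of GFP+ cells and between 1.04% and 1.22% of GFP− cells in these settings.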

Other observations

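The tests of depth on ribosomal protein genes, of RNA from GFP− enterocytes and of repeat reads were chosen only after the result was seen. Within the enterocyte-like clusters, 18 GFP+ cells (mostly in clusters 2 and 7) and 77 GFP− cells (in clusters 2 and 3) had an enterocyte list median log2 ratio of -0.12, against -0.98 over all cells. Their median depths were 1.93 and 0.891 in units of 1000000 non-mitochondrial counts. Apoa1 was at 6418 CPM in these GFP+ cells and 6982 CPM in the GFP− cells, while Fabp1, the liver-type fatty acid binding protein gene, was at 24911 against 6201 CPM. Without the top cell of each group Apoa1 was at 4323 and 6241 CPM and Fabp1 at 15392 and 5767 CPM. The fetal and repair list had 8 of 11 members higher in the GFP+ cells with a median of 1.97, and the p53 target list 9 of 15 with a median of 0.97, while the revival stem cell list had 2 of 5 members higher (-0.85) and the basement membrane and wound edge list 5 of 10 (0.10). The clusters were named by these same enterocyte genes, and clusters with revival stem cell markers were set apart. That choice of cells can itself set the medians of the enterocyte and revival stem cell lists. S100a6 was read in all 18 GFP+ cells and 40 of the 77 GFP− cells, at 165.2 and 389.5 CPM (101.3 and 132.8 without the top cell of each group), and Mdm2 in 13 and 14 cells, at 14.7 and 23.5 CPM, which turned to 9.27 and 3.23 without the top cells. F3 was read in 17 of the 18 GFP+ cells and 7 of the 77 GFP− cells at 36.1 and 0.499 CPM, and Krt18 in 16 and 12 cells at 133.2 and 12.05 CPM (73.1 and 1.602 without the top cells). These levels were 7.04% (F3) and 15.9% (Krt18) of those in GFP+ cells of the revival stem cell-like clusters, and Krt19 reached 41.6%. Clu itself was at 18.7 against 8.32 CPM, and at 5.39 against 4.95 CPM without the top cells.

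Genes of the Y chromosome were read in both groups (Ddx3y in 43 GFP+ and 21 GFP− cells, Eif2s3y in 54 and 13), and Xist had 50 and 64 reads in all. Over all cells, the median GFP+ cell had a summed enterocyte list level of 21137 CPM (quartiles 7856 and 49776) and the median GFP− cell 33810 CPM (21304 and 47544).

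Ribosomal protein genes were higher in GFP+ cells for 73 of 75 members with a median log2 ratio of 2.82. Gene length was taken over all annotated exons of a gene, with a median of 1739 bases for the ribosomal protein genes. Other genes matched on that length and on mean level had a median of 0.0339, and the highest of 10000 draws was 1.31. This argues against a bias by that length. It can exceed the length of a gene's mRNA, which was not matched, so a bias by mRNA length stays open. Depth was not decided, since thinning leaves the expected CPM of each cell as it was and only evens the weight of cells. The median was 2.70 (2.14 to 3.10) with every cell thinned to 510000 reads, and 2.70 with cells weighted equally. Mitochondrial share stays open. Among cells with 50 to 80% mitochondrial counts the median was 2.09 (1.37 to 2.62), which lies above the bound of 2 set in advance by less than its spread, and the median summed levels of GFP+ and GFP− cells were 18881 and 4349 CPM at 30 to 50%, 7828 and 3055 CPM at 50 to 65%, 7350 and 2581 CPM at 65 to 80%, 7261 and 3889 CPM above 80%, but 19052 and 27361 CPM up to 30%, where there were 2 GFP− cells. Plate cannot be told apart from the group, since 0 plates held cells of both. A difference in the kinds of cells stays open too, since within the enterocyte-like clusters the median was 1.05, with 50 of 75 members higher.

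The most abundant enterocyte transcripts were read in nearly all GFP+ cells (Apoa1 in 95 of 96), others in fewer (Slc2a2 in 36, Mep1a in 19). RNA or index-hopped reads from GFP− enterocytes stay open, since the median level of the 19 genes in the 78 GFP+ cells outside the enterocyte-like clusters was 29.9% of that in GFP− cells (19.1 to 61.4%), and 19.9% without the top GFP+ cell of each gene, so that the value lies above the bound of 10% but not above that of 25% by more than its spread. A subset of enterocytes among the GFP+ cells may carry part of the reads, but the test did not decide: 19.8% of GFP+ cells (19 of 96) had a summed level below 10% of the GFP− median, between the bounds of 10% and 50%. The 78 cells also include GFP+ cells of the unnamed clusters 5 and 6. In the 52 GFP+ cells of the revival stem cell-like clusters Apoa1 was at 914.4 CPM, or 335.1 CPM without its top cell. It was at 6982 CPM in the GFP− cells of the enterocyte-like clusters. No other member of the list was compared in those 52 cells. Absorptive RNA made by cells of the other clusters was not separately tested.

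Olfactory and vomeronasal receptor genes, 1357 in the table, took 4293 CPM in GFP− cells and 1745 CPM in GFP+ cells, a log2 ratio of -1.30. The satellite repeat genes Gm10800 and Gm10801 had a log2 ratio of -1.17 (44902 against 19925 CPM), a difference of 0.127. Genomic DNA or repeat reads taking a larger share in cells with less mRNA would give such a small difference, but the test does not decide. Random lists matched to the low-level B and plasma cell and tuft lists had medians of -1.43 and -0.88, against 0.12 for the enterocyte list. The receptor genes were thus not set apart from other low-level genes. Expression of a few receptor genes stays open, since the 10 receptor genes with most counts held 54.4% of the GFP− receptor counts, between the bounds of 50% and 80%, and the log2 ratio without those genes was -0.96. No other biological explanation was tested. Part of the signal may not be mRNA, in GFP+ as in GFP− cells, since receptor and satellite genes had reads in both groups. This would bear on genes near the detection limit. Whether it touches genes at higher levels was not tested. Pi4ka, named in GFP− cells at 269.6 CPM, was among the top 10 genes of the unnamed cluster 5, as was the receptor gene Olfr1030.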
